A study of Mus musculus with 6 samples.

How the data were processed

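Single-cell RNA was measured with CEL-Seq2 in its plate-based form (SORT-seq), in which single cells are sorted into wells of 384-well plates and transcripts are captured by their polyA tail, read at the 3' end and tagged with a unique molecular identifier (UMI) of 6 bases. The 6 samples were 6 plates, 3 from Matrigel and 3 from collagen I, per the labels. Before sorting, organoids were isolated with collagenase and dissociated with TrypLE, per the labels' protocols. The authors deposited 3 tables per plate. The deposited UMI count table gives whole-number counts of distinct UMIs per gene and well, not normalized, and a second deposited table gives read counts before UMIs were collapsed. The third deposited table holds estimated counts of transcripts, which were checked to equal the UMI counts corrected for UMI saturation, ln(1 - n/4096)/ln(1 - 1/4096) for n UMIs. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation and any use of the strand are not given in the sources used here. The tables hold older gene symbols, such as Cyr61 for Ccn1 and Ctgf for Ccn2, and rows for 86 ERCC spike-in RNAs and for eGFP, which are named here as in the tables.

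UMI counts were the main input. A well was kept as a cell with at least 1000 UMIs of nuclear-encoded endogenous genes, at least 500 such genes, a mitochondrial share of at most 40% of endogenous UMIs and an ERCC share of at most 25% of all UMIs. Of 2304 wells 942 held 1000 UMIs, and 887 were kept, after removal of 50 wells for ERCC share, 4 for mitochondrial share and 1 for gene number. Each well was meant to hold a single sorted cell and no doublet caller was run. The 8 cells above 3 times their plate's median UMI count were left out in an alternative. Reads per UMI ranged from 4.00 to 23.5 over the plates. ERCC rows stayed out of library sizes. The plates held between 2132689 and 11517674 UMIs in kept cells, so that a gene at 1 CPM rested on few UMIs on the smallest plates, and the biological coefficient of variation between plates was 13.2%.

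Cells are not replicates, so that counts were summed over the kept cells of each plate. The sums were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr, the quasi-likelihood fit and test without covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values are UMIs per 1000000 library UMIs of a plate after TMM scaling. Standard errors are on the log2 scale, and positive log2 fold changes mean higher in collagen I. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, over the lists with at least 5 tested members, and again with an estimated correlation and with fry. Fry tests whether the members of a list move on balance in a given direction and does not compare them with other genes. The tests were checked on counts drawn from the means and library sizes of this comparison over 10547 genes. Of genes changed 2-fold, 74 of 95 were called in the right direction, and of those changed 4-fold, 98 of 98. Of the calls 10 were on unchanged genes (5.50%), the raised simulated list was called and 0 other lists were. With no gene changed, 1 gene and 0 lists were called. Each simulated gene was drawn independently, so that these results cannot show how often camera wrongly calls lists of correlated genes.

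The genes named were fixed by a rule written before the data were examined. They are the 10 largest rises and the 10 largest falls among changed genes with a mean of at least 20 CPM and non-overlapping groups, a set of 25 anchor genes, and up to 4 members of each list with the smallest p. The eGFP row was measured beside the anchors. The 36 lists, also fixed before, were Lgr5 stem cell, fetal-like and regenerative, YAP/TEAD targets, Wnt targets, integrins, focal adhesion and actin linkers, SRF/MRTF and contractile targets, mechanosensitive and calcium channels, calcium signalling and buffering, colonocyte and enterocyte, goblet, Paneth and deep crypt secretory, enteroendocrine, tuft, G1/S, G2/M, epithelial junctions, epithelial-mesenchymal transition, laminins and basement membrane, proteases and matrix remodelling, EGFR/MAPK output, NF-kB and inflammatory, interferon response, TGF-beta and BMP targets, hypoxia, glycolysis, cholesterol synthesis, integrated stress and unfolded protein response, heat shock and dissociation stress, antioxidant and NRF2, mitochondrially encoded, cytosolic ribosomal proteins, squamous and keratin, and fibroblast, immune and endothelial markers. They were drawn from general knowledge of these pathways and not from these libraries.

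For shares of cells and per-cell list shares, each kept cell was thinned without replacement to 2000 nuclear UMIs, and 21 shallower cells were left out. Relations between shares of 2 lists left out the members of both. Plate values were compared by exact two-sided permutation tests, for which 3 plates against 3 allow no p under 0.1. Cells were clustered with scanpy 1.11.5 on 2000 variable genes, 30 principal components and 15 neighbours at a Leiden resolution of 0.6, after scaling to 10000 counts per cell and log transformation. A cluster was named only from markers fixed in advance, with at least 3 of them at 2-fold or more over the other cells. The goblet-like name went to the cluster with most such goblet markers. It was compared between matrices only if no other class had more markers among its 10 leading genes. Coordinates come from GENCODE release M21 for mm10.

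Alternatives fixed before were RLE factors or none, other filters on low counts, DESeq2 1.42.0, the plate number as a replicate block, leaving out each plate, read counts or transcript counts (rounded after summing) as input, other limits on UMIs and mitochondrial share, all wells, removal of cells with many UMIs, thinning of cells or of plate sums, other thinning depths and other clusterings. Added after the data were seen were leaving out both plates under 40 cells, drawing 25 cells per plate, keeping cells at or under their plate's median mitochondrial share, and clustering without the changed genes. Matrigel and collagen plates share replicate numbers, which are not stated to pair them.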

Results

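The transcriptomes of single cells from mouse colorectal cancer organoids were measured after a change of the surrounding matrix. The organoids, which are epithelial cultures grown from tumour-bearing colons, carried loss of Apc and Tp53 and an oncogenic Kras allele, together with a Confetti colour reporter and an Lgr5 allele that drives a diphtheria toxin receptor and eGFP. After 3 days in Matrigel, a basement membrane extract rich in laminin, intact organoids were released and placed for 1 day either in Matrigel again or in fibrillar type I collagen at 1 mg/ml. The title of the series asks how mechanosensitive calcium channels and integrins take part in the reprogramming of colorectal cancer cells to a fetal-like state. The comparison of collagen I with Matrigel addresses which genes and cell states differed between the matrices.

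Each matrix was represented by 3 plates of 384 wells with single sorted cells. Cells passing the quality limits numbered 193, 30 and 86 on Matrigel plates 1 to 3 (309 cells) and 29, 272 and 277 on collagen plates 1 to 3 (578 cells). The summed unique molecular identifiers (UMIs) of these cells were 7970577, 2175162 and 4374435 for Matrigel and 2132689, 10672102 and 11517674 for collagen I. Median nuclear UMIs per cell were 40807 ± 7813 in Matrigel and 40559 ± 10922 in collagen I (SD, n = 3 plates, exact two-sided permutation p = 1), and the median mitochondrial share was 13.3% ± 0.833 and 13.3% ± 1.82 (SD, n = 3, exact permutation p = 1). The smallest p that 3 plates against 3 allow is 0.1. The plates are not stated to come from separate cultures, so that all p-values below measure only the spread between these plates, which may be technical.

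Cells from collagen I had more RNA of fetal-like and regenerative epithelial genes and less of Lgr5 stem cell genes than cells from Matrigel. Ly6a, which encodes the surface protein Sca-1 and marks fetal and regenerating intestinal epithelium, rose from 453 ± 115 to 1938 ± 138 CPM (counts per 1000000 UMIs, mean ± SD, n = 3 plates; log2 fold change 2.10, SE 0.16, edgeR adjusted p = 3.33e-05). Lgr5, the receptor that marks crypt base stem cells, fell from 86.7 ± 7.93 to 42.3 ± 2.89 CPM (log2 fold change -1.01, SE 0.12, edgeR adjusted p = 4.78e-04), and eGFP transcripts fell from 274 ± 13.8 to 81.5 ± 10.2 CPM (log2 fold change -1.73). The labels name eGFP in the Lgr5 allele, and the Confetti reporter also encodes fluorescent proteins, so that the origin of each eGFP read is not given in the sources used here. Lists of genes of cell adhesion, actin contractility, inflammation, hypoxia and glycolysis were also called higher in collagen I by limma camera at its preset correlation. With an estimated correlation limma camera called 0 of 31 lists, 10 of which had an unadjusted p under 0.05, and limma fry called 14.

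Among 10685 genes tested with edgeR's quasi-likelihood test, 1163 changed at a Benjamini-Hochberg adjusted p under 0.05, of which 734 were higher and 429 lower in collagen I. Changes larger than 2-fold comprised 225 rises and 144 falls. At an unadjusted p under 0.05 there were 2849 genes, against 534 by chance, and the values of the groups did not overlap for 3457 genes (32.3%, against 10% by chance). Without normalization factors 1145 genes changed and the share of higher genes was 45.6% in place of 63.1%. The number of changed genes was 643 without Matrigel plate 1, 482 without Matrigel plate 3, 1929 without collagen plate 1, 500 without collagen plate 2 and 623 without collagen plate 3. It was 2268 without both plates that held fewer than 40 cells. All Matrigel plates were sequenced on 1 flow cell and the collagen plates on 2 others, so that matrix and flow cell cannot be told apart and no value within a batch can be given.

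Of the 10 largest rises among well-expressed genes, the chemokine genes Cxcl1 (log2 fold change 2.96, SE 0.30) and Cxcl16 (2.81, SE 0.32), the trefoil factor gene Tff1 (2.95, SE 0.62) and the annexin genes Anxa3 (2.84, SE 0.26) and Anxa1 (2.37, SE 0.19) led. They were followed by 4732456N10Rik (2.31), a keratin gene annotated as Krt90 and outside the fixed keratin list, the hypoxia-inducible mitophagy gene Bnip3 (2.29), Emp1 (2.25), Ly6d (2.24) and 9030619P08Rik (2.12). The 10 largest falls were those of the mitochondrial aldehyde dehydrogenase Aldh1b1 (log2 fold change -2.53, SE 0.12), the lectin Itln1 (-2.52, SE 0.53), Prelp (-2.25), Rap1gap (-2.07), the guanylin family genes Guca2b (-2.02) and Guca2a (-1.64), Rorb (-1.93), Ifitm1 (-1.84), eGFP (-1.73) and Lypd8 (-1.70). Aldh1b1 fell from 197 ± 17.3 to 33.9 ± 1.67 CPM (n = 3, edgeR adjusted p = 1.28e-06). Anxa1 rose from 156 ± 35.5 to 798 ± 183 CPM (n = 3, edgeR adjusted p = 4.48e-05). Tff1 varied widely between collagen plates, at 509, 107 and 79.5 CPM, and Itln1 between Matrigel plates, at 131, 83.2 and 407 CPM. With 1 plate left out, their log2 fold changes ranged from 1.73 to 3.38 and from -3.11 to -1.58. When each plate was left out in turn, 17 of these 20 genes stayed past the threshold. Tff1 lost it without Matrigel plate 1 (edgeR adjusted p = 0.0579) and without Matrigel plate 3 (0.0651), 4732456N10Rik without Matrigel plate 1 (0.0522), and Rorb without Matrigel plate 2 (0.0579), Matrigel plate 3 (0.0503), collagen plate 2 (0.0877) and collagen plate 3 (0.0771).

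In the mouse build mm10 with GENCODE release M21, Ly6a spans chromosome 15 positions 74994877 to 74998031 on the minus strand, Lgr5 chromosome 10 positions 115450311 to 115587780 on the minus strand, Anxa1 chromosome 19 positions 20373428 to 20390944 on the minus strand and Aldh1b1 chromosome 4 positions 45799022 to 45804604 on the plus strand. All 4 are protein-coding genes, and the deposited counts are per gene without an exon or transcript. Many of the genes named overlap another annotated gene, among them Lgr5, Anxa1, Tff1, Cxcl16 and Itgb4 on the opposite strand and Itga6, Tmc4, Lamb3 and Ifitm2 on the same strand. Whether counting used the strand is not given in the sources used here, so that their values are uncertain to that extent. The same holds for close paralogs such as Ifitm1, Ifitm2 and Ifitm3, the Guca2 genes, the keratins and the actins.

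**Figure D1:**
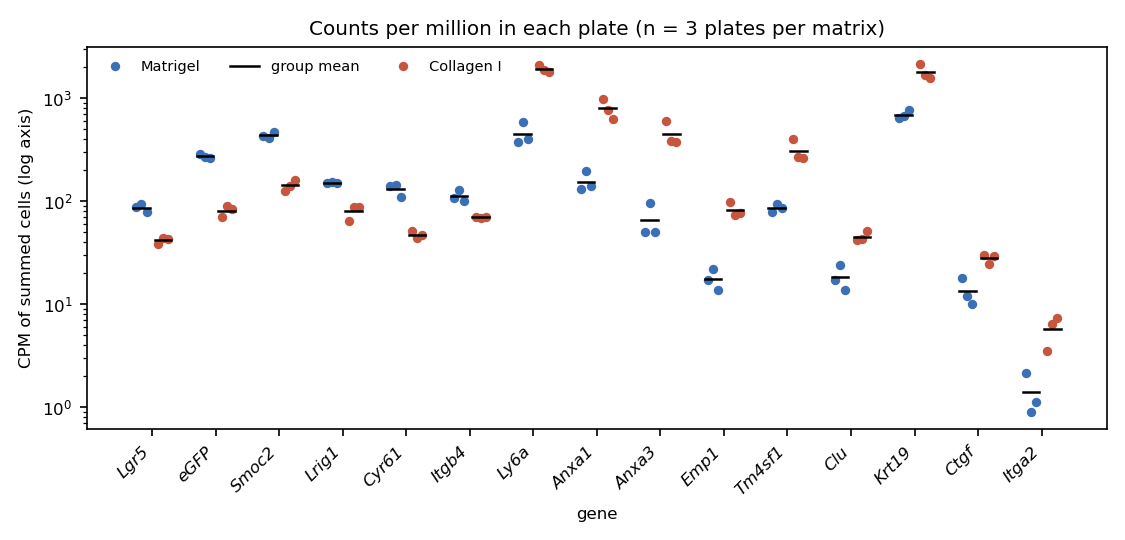
CPM of the summed cells of each plate (y axis, log scale) for 15 genes (x axis), with a point per plate, blue for Matrigel and red for collagen I, and a bar at the mean of 3 plates. In each gene shown the plates of the groups did not overlap, with mean Ly6a at 453 CPM in Matrigel and 1938 CPM in collagen I and mean Lgr5 at 86.7 and 42.3 CPM.

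Fetal-like and regenerative genes had the lowest p of the 31 lists tested by limma camera at its preset correlation, though not with an estimated correlation. Of its 31 tested members, 19 rose and 1 fell, against 23 and 1 when adjusted over the list alone. The median log2 fold change of its members was 0.98 (limma camera adjusted p = 1.88e-10, adjusted p = 0.146 with an estimated correlation). Rising members included Anxa3, Emp1, Tm4sf1 (86.8 ± 8.51 to 311 ± 77.0 CPM, n = 3, log2 fold change 1.84) and Clu, a gene of revival stem cells, which rose from 18.5 ± 5.30 to 45.4 ± 4.88 CPM (n = 3, log2 fold change 1.36). The member that fell was Cyr61, the matricellular gene also named Ccn1. Tacstd2, the fetal marker also known as Trop2, was at 121 ± 12.9 and 158 ± 4.84 CPM (n = 3, log2 fold change 0.37, edgeR adjusted p = 0.0533) and passed the threshold without collagen plate 1 (0.0425).

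Lgr5 stem cell genes went the other way. Of 21 tested members 7 fell and 1 rose, against 12 and 1 when adjusted over the list alone. Its median was -0.45 on the log2 scale (limma camera adjusted p = 7.12e-05, adjusted p = 0.209 with an estimated correlation), and -0.29 without both plates under 40 cells. Beside Lgr5, falls included Smoc2 (439 ± 30.1 to 143 ± 18.2 CPM, n = 3, log2 fold change -1.61) and Lrig1 (152 ± 2.89 to 80.4 ± 13.8 CPM, n = 3, log2 fold change -0.89). Ascl2, the transcription factor of crypt base stem cells, was at 155 ± 21.9 and 121 ± 7.11 CPM (n = 3, log2 fold change -0.35, edgeR adjusted p = 0.102). Olfm4 had 1 UMI over all Matrigel cells and 0 over all collagen cells and was not tested.

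Wnt targets were lower on balance, with 5 members down and 2 up among 15 tested, against 8 and 2 when adjusted over the list alone. Members had a median log2 fold change of -0.43 (limma camera adjusted p = 2.14e-03, adjusted p = 0.209 with an estimated correlation). Prox1 (log2 fold change -1.49) and the Wnt deacylase Notum (-1.25) fell, while the hyaluronan receptor Cd44 rose (1.15). Axin2, a feedback inhibitor of Wnt signalling, was at 207 ± 5.44 and 148 ± 34.5 CPM (n = 3, log2 fold change -0.46, edgeR adjusted p = 0.0712), and passed the threshold without collagen plate 1 (0.0495). Lists shared some members, since Cd44 belonged to the fetal-like, Wnt and mesenchymal lists, Ctgf to the fetal-like, YAP/TEAD and TGF-beta lists, Lgr5 to the stem cell and Wnt lists, and 2 genes to the hypoxia and glycolysis lists.

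Integrin genes, whose products bind matrix proteins, changed member by member. Of 11 tested 4 rose and 1 fell, against 6 and 1 when adjusted over the list alone. The median log2 fold change of its members was 0.32 (limma camera adjusted p = 0.0117, adjusted p = 0.146 with an estimated correlation). The collagen-binding subunit gene Itga2 rose from 1.40 ± 0.682 to 5.76 ± 2.01 CPM (n = 3, log2 fold change 1.95, SE 0.41, edgeR adjusted p = 0.0115), and the call was lost without Matrigel plate 3 (0.0663), collagen plate 2 (0.0624) or collagen plate 3 (0.0749). Itga3 rose by 0.74 on the log2 scale. Itgb4, the laminin-binding subunit gene of hemidesmosomes, fell from 112 ± 14.5 to 69.9 ± 1.51 CPM (n = 3, log2 fold change -0.67, SE 0.12, edgeR adjusted p = 4.94e-03). Itga6 was at 26.5 ± 1.82 and 35.7 ± 3.87 CPM (n = 3, log2 fold change 0.45, edgeR adjusted p = 0.0570) and Itgb1 at 217 ± 21.0 and 270 ± 22.6 CPM (n = 3, log2 fold change 0.32, edgeR adjusted p = 0.0955), and without collagen plate 1 both passed the threshold (0.0199 and 0.0194). Itga5 had 1 UMI in Matrigel and 4 in collagen I and was not tested.

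Focal adhesion and actin linker genes rose in 11 and fell in 1 of 27 cases, against 17 and 2 when adjusted over the list alone. Its median was 0.41 on the log2 scale (limma camera adjusted p = 9.88e-07, adjusted p = 0.146 with an estimated correlation). The GTPase gene Rhoc rose from 12.5 ± 2.10 to 49.5 ± 4.70 CPM (n = 3, log2 fold change 2.00), the filamin gene Flnb rose by 1.05 on the log2 scale, and the caveolin gene Cav1 rose from 0.386 ± 0.141 to 4.28 ± 1.18 CPM (n = 3). Among SRF/MRTF and contractile targets 11 of 18 rose and 0 fell, against 11 and 1 when adjusted over the list alone. Members had a median log2 fold change of 0.61 (limma camera adjusted p = 1.58e-04, adjusted p = 0.146 with an estimated correlation). Actb rose from 2214 ± 50.6 to 3292 ± 115 CPM (n = 3, log2 fold change 0.57) and the calponin gene Cnn2 from 68.1 ± 3.90 to 151 ± 21.1 CPM (n = 3, log2 fold change 1.13).

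YAP/TEAD targets, read-outs of a mechanically regulated pathway, rose in 7 and fell in 1 of 24 cases, against 8 and 2 when adjusted over the list alone. The median log2 fold change of its members was 0.37 (limma camera adjusted p = 2.57e-03, adjusted p = 0.306 with an estimated correlation). The canonical targets Ctgf and Cyr61 moved in opposite directions. Ctgf, also named Ccn2, rose from 13.4 ± 4.11 to 27.9 ± 2.91 CPM (n = 3, log2 fold change 0.98, SE 0.21, edgeR adjusted p = 0.0130), a call lost without Matrigel plate 3 (0.0592) or collagen plate 3 (0.0514). Cyr61 fell from 132 ± 19.6 to 47.6 ± 3.61 CPM (n = 3, log2 fold change -1.48, SE 0.13, edgeR adjusted p = 8.91e-05). Ajuba (0.79) and Myof (0.73) also rose on the log2 scale. In the directional test of fry in limma the list was not called (adjusted p = 0.0757).

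Few channel transcripts passed the test at this depth. In the list of mechanosensitive and calcium channels, 0 of 17 tested members rose and 1 fell, with the same counts when adjusted over the list alone (limma camera adjusted p = 0.893). The member that fell was Tmc4 (120 ± 7.24 to 80.7 ± 5.15 CPM, n = 3, log2 fold change -0.56, edgeR adjusted p = 7.66e-03), and the call was lost without collagen plate 2 (0.0553). Piezo1, a stretch-activated cation channel, was at 1.32 ± 0.544 and 2.68 ± 0.704 CPM (n = 3, log2 fold change 0.75, SE 0.45, edgeR adjusted p = 0.316). Piezo2 had 1 UMI in Matrigel and 0 in collagen I, and Trpv4 had 2 and 5, so that neither was tested. For calcium signalling and buffering genes, 4 of 18 rose and 0 fell, against 8 and 0 when adjusted over the list alone. Its median was 0.28 on the log2 scale (limma camera adjusted p = 0.0148, adjusted p = 0.146 with an estimated correlation). The calcium pump gene Atp2b1 rose from 118 ± 16.8 to 177 ± 2.77 CPM (n = 3, log2 fold change 0.60, edgeR adjusted p = 9.35e-03), which was lost without Matrigel plate 3 (0.0562). The other 3 rises, of Atp2a2, Calm1 and Capn2, were also lost without that plate (0.0571, 0.0905 and 0.114), and each in at least 3 of the other 5 leave-outs.

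**Figure D2:**
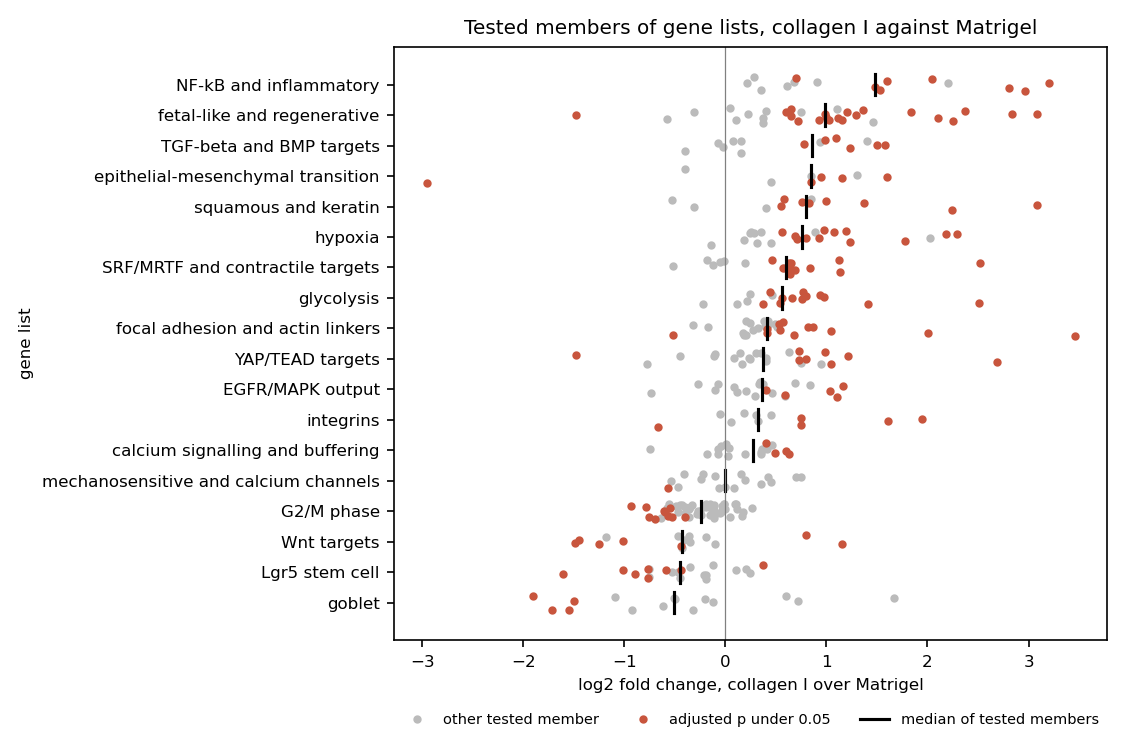
Log2 fold change of collagen I over Matrigel (x axis) for the tested members of the 17 gene lists past the threshold and of the channel list (y axis), red where the edgeR adjusted p was under 0.05 and grey otherwise, with a black bar at the median of each list. The medians ran from -0.51 for goblet genes to 1.48 for NF-kB and inflammatory genes, and the channel list lay near 0.

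Inflammatory genes had the highest list median. In the NF-kB and inflammatory list 8 of 15 tested members rose and 0 fell, against 13 and 0 when adjusted over the list alone. Members had a median log2 fold change of 1.48 (limma camera adjusted p = 1.95e-08, adjusted p = 0.146 with an estimated correlation). Cxcl1 rose from 7.36 ± 0.32 to 61.6 ± 27.4 CPM, the NF-kB inhibitor Nfkbia from 43.7 ± 8.20 to 131 ± 26.8 CPM (log2 fold change 1.53) and Tnf from 14.2 ± 4.07 to 39.2 ± 12.6 CPM (log2 fold change 1.48, n = 3 for each). TGF-beta and BMP targets rose in 6 and fell in 0 of 14 cases, against 8 and 0 when adjusted over the list alone. The median log2 fold change of its members was 0.86 (limma camera adjusted p = 9.80e-04, adjusted p = 0.146 with an estimated correlation). Pmepa1, a feedback inhibitor of TGF-beta signalling, rose by 1.51 on the log2 scale. EGFR/MAPK output genes rose in 5 and fell in 0 of 20 cases, against 6 and 1 when adjusted over the list alone. Its median was 0.36 on the log2 scale (limma camera adjusted p = 2.35e-03, adjusted p = 0.383 with an estimated correlation). Ier3 rose by 1.03 and Epha2 by 1.16 on the log2 scale. The EGFR/MAPK list was not called by limma fry (adjusted p = 0.0812).

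Genes of low oxygen and of sugar metabolism rose together. Hypoxia genes rose in 12 and fell in 0 of 22 cases, against 14 and 0 when adjusted over the list alone. Members had a median log2 fold change of 0.76 (limma camera adjusted p = 1.95e-08, adjusted p = 0.146 with an estimated correlation), which was 0.46 with 25 cells drawn per plate (3 of 20 rose) and 0.48 with every cell thinned to 2000 UMIs (5 of 15 rose). Bnip3 rose from 9.54 ± 0.0929 to 44.4 ± 16.8 CPM, the oxygen-sensing hydroxylase gene Egln3 by 1.78 and Fam162a by 0.93 on the log2 scale (n = 3). Glycolysis genes rose in 12 and fell in 0 of 17 cases, against 13 and 0 when adjusted over the list alone. The median log2 fold change of its members was 0.56 (limma camera adjusted p = 2.45e-07, adjusted p = 0.146 with an estimated correlation). The lactate transporter gene Slc16a3 rose from 47.2 ± 15.7 to 127 ± 1.47 CPM (n = 3, log2 fold change 1.41) and the phosphoglycerate mutase gene Pgam1 from 623 ± 61.9 to 1052 ± 43.8 CPM (n = 3, log2 fold change 0.75).

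Squamous and keratin genes rose in 8 and fell in 0 of 12 cases, against 9 and 0 when adjusted over the list alone. Its median was 0.79 on the log2 scale (limma camera adjusted p = 5.04e-06, adjusted p = 0.146 with an estimated correlation). Krt19 rose from 696 ± 60.4 to 1797 ± 300.5 CPM (n = 3, log2 fold change 1.37) and Krt7 from 690 ± 7.93 to 1375 ± 161 CPM (n = 3, log2 fold change 0.99), whereas the log2 fold change of Krt20, a marker of mature colonocytes, was -0.53 (SE 0.51, edgeR adjusted p = 0.550). In the epithelial-mesenchymal transition list 4 of 9 tested members rose and 1 fell, with the same counts when adjusted over the list alone. Members had a median log2 fold change of 0.85 (limma camera adjusted p = 3.13e-03, adjusted p = 0.152 with an estimated correlation). The call was lost without collagen plate 1 (limma camera adjusted p = 0.0963). The rising members were Ahnak (0.85), Cd44, and the laminin subunit genes Lamb3 (1.60) and Lamc2 (20.7 ± 1.87 to 41.5 ± 5.18 CPM, n = 3, log2 fold change 0.95), which epithelial cells also express, and the basement membrane collagen gene Col4a1 fell (log2 fold change -2.95). The mesenchymal gene Vim had 19 UMIs in Matrigel and 6 in collagen I and was not tested, and Cdh1, the epithelial cadherin, was at 339 ± 22.9 and 375 ± 31.8 CPM (n = 3, log2 fold change 0.15, edgeR adjusted p = 0.419).

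Goblet genes fell in 4 and rose in 0 of 15 cases, with the same counts when adjusted over the list alone. The median log2 fold change of its members was -0.51 (limma camera adjusted p = 0.0148, adjusted p = 0.383 with an estimated correlation). Without Matrigel plate 3 the list lost its call (limma camera adjusted p = 0.151), and limma fry did not call it (adjusted p = 0.0945). Klk1 (22.3 ± 3.29 to 6.06 ± 1.78 CPM, n = 3, log2 fold change -1.90) and Bcas1 (22.3 ± 2.99 to 6.81 ± 2.95 CPM, n = 3, log2 fold change -1.55) were among the falls, and the mucin gene Muc2 was at 1.42 ± 2.26 and 3.80 ± 4.95 CPM (n = 3, edgeR adjusted p = 0.320). Paneth and deep crypt secretory genes fell in 2 and rose in 0 of 6 cases, Itln1 and Mmp7 (log2 fold change -0.91), against 3 and 1 when adjusted over the list alone (limma camera adjusted p = 0.17). Colonocyte and enterocyte genes rose in 3 and fell in 3 of 12 cases, against 4 and 3 when adjusted over the list alone (limma camera adjusted p = 0.924), with Guca2a and Guca2b among the falls. Of 4 tested enteroendocrine genes 1 rose, against 1 up and 1 down when adjusted over the list alone, and of 2 tuft genes 1 rose, also when adjusted over the list alone, which were too few for a list test. Chga, the enteroendocrine marker, had 6 UMIs in Matrigel and 0 in collagen I. Among the other cell types that a sample could hold, fibroblast, immune and endothelial lists had 1, 1 and 3 tested members, of which 0 changed by edgeR over all genes and 0 by DESeq2. At an unadjusted p under 0.05 there were 0, 1 and 1 such genes, and 1 immune gene rose when adjusted over the list alone.

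In the G2/M list 10 of 52 genes fell and 0 rose, against 14 and 0 when adjusted over the list alone. Its median was -0.24 on the log2 scale (limma camera adjusted p = 1.58e-04, adjusted p = 0.455 with an estimated correlation). The list was not called by fry in limma (adjusted p = 0.148). Hmgb2 fell from 1010 ± 2.70 to 589 ± 143 CPM (n = 3, log2 fold change -0.78) and Ckap2l from 79.2 ± 7.42 to 47.4 ± 8.25 CPM (n = 3, log2 fold change -0.75). Mki67, the proliferation marker, was at 266 ± 10.4 and 236 ± 23.2 CPM (n = 3, log2 fold change -0.17, edgeR adjusted p = 0.345). In the G1/S list 2 of 41 genes fell and 0 rose, against 1 and 0 when adjusted over the list alone (limma camera adjusted p = 0.431).

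The remaining lists were not called. Epithelial junction genes rose in 6 and fell in 1 of 27 cases, the claudin gene Cldn15 (log2 fold change -1.24), against 9 and 1 when adjusted over the list alone (limma camera adjusted p = 0.117). Laminin and basement membrane genes rose in 3 and fell in 1 of 10 cases, against 5 and 1 when adjusted over the list alone (limma camera adjusted p = 0.206), and protease genes rose in 3 and fell in 1 of 15 cases, against 4 and 1 when adjusted over the list alone (limma camera adjusted p = 0.153, and 5.65e-03 by fry). Interferon response genes rose in 3 and fell in 1 of 17 cases, against 5 and 1 when adjusted over the list alone (limma camera adjusted p = 0.568), where Ifitm3 fell from 1299 ± 163 to 508 ± 42.1 CPM (n = 3, log2 fold change -1.35). Cholesterol synthesis genes rose in 2 and fell in 2 of 25 cases, against 3 and 2 when adjusted over the list alone (limma camera adjusted p = 0.703). Antioxidant genes rose in 1 and fell in 2 of 19 cases, against 2 and 2 when adjusted over the list alone (limma camera adjusted p = 0.244). Heat shock and dissociation stress genes rose in 5 and fell in 5 of 26 cases, against 6 and 7 when adjusted over the list alone (limma camera adjusted p = 0.856). The immediate-early genes Fos (log2 fold change -1.53), Fosb (-2.21) and Jun (-1.33) were among the falls, and 3 of the 5 rises, Ier3 among them, were of immediate-early genes as well. None of 24 integrated stress and unfolded protein response genes, 13 mitochondrially encoded genes and 52 cytosolic ribosomal protein genes changed by edgeR over all genes or when adjusted over the list alone (limma camera adjusted p = 0.893, 0.893 and 0.399). At an unadjusted p under 0.05 there were 3, 1 and 1 of them, and DESeq2 called 1, 0 and 0. The median and the list test differed in sign for the channel and stress response lists, and the heat shock list had a positive median and a negative mean.

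In all, camera with a preset correlation of 0.01 called 17 of 31 tested lists, 13 higher and 4 lower, and 0 lists were called by camera with an estimated correlation, where the smallest adjusted p was 0.146 and 10 lists had an unadjusted p under 0.05. The directional test of limma fry called 14 lists, 13 of them shared with camera.

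At the level of single cells, the fetal-like list was higher in collagen I at each percentile measured. At 2000 UMIs per cell the 10th, 50th and 90th percentiles of the share of UMIs in that list were 0.652% ± 0.0729, 1.06% ± 0.0629 and 1.66% ± 0.0946 in Matrigel and 1.02% ± 0.0874, 1.65% ± 0.132 and 2.50% ± 0.0400 in collagen I (SD, n = 3 plates, exact permutation p = 0.1 for each). For stem cell genes the percentiles were 0.183% ± 0.0289, 0.375% ± 0.0250 and 0.688% ± 0.0340 in Matrigel and 0.0967% ± 0.0058, 0.267% ± 0.0289 and 0.483% ± 0.0289 in collagen I (SD, n = 3, exact permutation p = 0.1 for each). For G2/M genes the 10th percentile was 0.213% ± 0.0115 in Matrigel and 0.237% ± 0.0058 in collagen I (SD, n = 3, exact permutation p = 0.1). This difference is smaller than 1 UMI of 2000 and rests on interpolation between whole UMI counts, so that no shift can be read from it. The 90th percentile was 1.57% ± 0.111 and 1.17% ± 0.121 (SD, n = 3, exact permutation p = 0.1), while the median was 0.65% ± 0.05 and 0.6% ± 0.0866 (exact permutation p = 0.6). Averaged over all UMIs of a cell, the stem cell list took 0.383% ± 0.0081 and 0.287% ± 0.0313, the fetal-like list 1.14% ± 0.108 and 1.75% ± 0.133, the YAP/TEAD list 0.0962% ± 0.0046 and 0.108% ± 0.0048 and the G2/M list 0.818% ± 0.0105 and 0.673% ± 0.0387 (SD, n = 3, exact permutation p = 0.1 for each, 0.125 adjusted over 5 lists). The G1/S list took 0.607% ± 0.0433 and 0.586% ± 0.0523 (SD, n = 3, exact permutation p = 0.6).

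**Figure D3:**
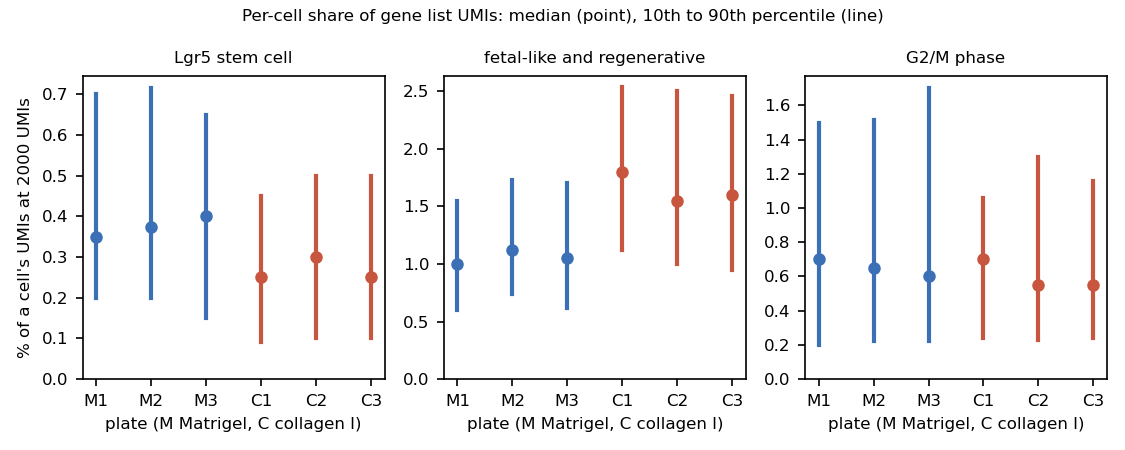
Percent of a cell's UMIs in the stem cell, fetal-like and G2/M lists at 2000 UMIs per cell (y axis) for each plate (x axis), with a point at the median cell and a line from the 10th to the 90th percentile, blue for Matrigel and red for collagen I. The mean of the plate medians was 1.06% in Matrigel and 1.65% in collagen I for fetal-like genes and 0.375% and 0.267% for stem cell genes.

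At the same depth, 44.1% ± 11.6 of Matrigel cells and 92.8% ± 1.35 of collagen cells had a Ly6a UMI, and 22.1% ± 2.32 and 59.7% ± 2.02 had an Anxa1 UMI (SD, n = 3 plates, exact two-sided permutation p = 0.1 for each). An Lgr5 UMI was found in 20.2% ± 5.18 and 10.0% ± 0.586 of cells, an eGFP UMI in 35.9% ± 6.43 and 15.3% ± 1.30 and a Cyr61 UMI in 25.6% ± 7.36 and 6.62% ± 2.75 (SD, n = 3, exact permutation p = 0.1 for each). Among 26 genes measured in this way the plates of the groups did not overlap for 9, with 3 higher and 6 lower in collagen I (chance share 10%), and the adjusted p was 0.289 for each of them. The 21 cells with fewer than 2000 UMIs were left out. Without thinning, a Ly6a UMI was found in 90.1% ± 6.90 of Matrigel and 100% of collagen cells, and an Lgr5 UMI in 78.5% ± 4.19 and 60.4% ± 2.34 (SD, n = 3). Both Lgr5 and Ly6a were found in 5.89% ± 2.33 and 6.99% ± 3.20 of thinned cells (SD, n = 3, exact permutation p = 0.8).

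Stem cell and fetal-like shares had negative rank correlations from cell to cell on all plates, some of them close to no relation. Whether they differed from no relation was not tested. The rank correlation within a plate was -0.188, -0.0635 and -0.0266 on the Matrigel plates and -0.0093, -0.314 and -0.217 on the collagen plates (exact permutation p = 0.5 for the difference of means, n = 3). UMIs of at least 3 G2/M genes were found in 94.6% ± 1.55 of Matrigel and 97.0% ± 2.68 of collagen cells at 2000 UMIs (SD, n = 3, exact permutation p = 0.3), a measure close to its ceiling whose direction turned with 1000 UMIs (-3.16 percentage points), 4000 UMIs (-0.256) or at least 2 genes (-0.266). The planned clustering gave a goblet-like cluster of 26 cells at each of 3 resolutions. Of its 10 leading genes 4 were goblet and 4 were Paneth markers, so that the name rests on a tie. It held 5.50% ± 1.05 of Matrigel and 2.24% ± 1.06 of collagen cells (SD, n = 3 plates, exact permutation p = 0.1). Its leading genes Itln1 and Guca2a differed between the matrices, so that its size may reflect their fall. It held 2 cells on Matrigel plate 2 and 1 on collagen plate 1. A goblet-like cluster of 52 cells, found when the changed genes were left out of clustering, held 7.74% ± 1.38 of Matrigel and 4.42% ± 1.49 of collagen cells (SD, n = 3 plates, exact permutation p = 0.1). This clustering was chosen after the data were seen, and 4 goblet and 4 Paneth markers were among the 10 leading genes of the cluster. Itln1 and Guca2a were again among these genes, and the cluster held 2 cells on Matrigel plate 2 and 1 on collagen plate 1. Another of the 7 clusters of the planned clustering had 13 fetal-like markers at 2-fold. It held 2.59%, 0% and 1.16% of cells on Matrigel plates 1 to 3 and 24.1%, 29.4% and 28.2% on collagen plates 1 to 3. Its leading genes Sprr1a and Anxa3 changed between the matrices, so that these sizes are no separate evidence.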

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

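The tests of flow cells, of dissociation stress as a whole and of Cyr61 against the other YAP/TEAD genes or with 15 members of the stress list, and the settings with 25 cells per plate and with cells of low mitochondrial share, were chosen only after the results were seen.

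Wells that were not kept as cells also held RNA, which did not enter the main measurement. They contained 1.14%, 3.03% and 1.86% of the nuclear UMIs of Matrigel plates 1 to 3 and 4.34%, 0.651% and 0.62% of those of collagen plates 1 to 3, in 191, 354, 298, 355, 112 and 107 wells. In these wells Ly6a was at 553, 745 and 360 CPM on the Matrigel plates and at 2143, 1871 and 1559 CPM on the collagen plates. Lgr5 was at 138, 67.8 and 83.2 CPM on the Matrigel plates and at 46.9, 33.1 and 114 CPM on the collagen plates, with overlapping groups. Anxa1 was at 239, 237 and 111 against 597, 580 and 422 CPM, and eGFP at 364, 136 and 291 against 23.4, 49.7 and 97.5 CPM. These wells held only 59036 to 85379 nuclear UMIs per plate, so that the Lgr5 values rest on few UMIs. Where their RNA came from was not tested, so that they are not independent evidence.

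The rise of fetal-like genes with the fall of Lgr5 stem cell genes was weighed against technical differences. The plates differed in cell number. With 25 cells drawn per plate the median log2 fold change of the fetal-like list was 0.87, against 0.98 with all cells. With plate sums thinned to the smallest plate it was 0.98. The rise was thus also seen at equal cell number or depth. A random draw of cells or UMIs leaves the expected CPM of a gene unchanged, so that these settings cannot decide whether either played a part. The median of the stem cell list was -0.36 with 25 cells per plate and -0.52 with plate sums thinned, against -0.45. Collagen plates on different flow cells differed over the changed genes by a median absolute log2 difference of 0.12 to 0.24, and plates of different matrices by 0.65 to 0.82. These genes were chosen for a difference between the matrices, so that such a gap was built in. Over all tested genes, collagen plates on different flow cells correlated at 0.957 and 0.993. Plates of different matrices correlated at 0.929 to 0.972, which overlaps only through collagen plate 1, with 29 cells. That plate correlated at 0.957 with collagen plate 3. With collagen plate 2, on its own flow cell, it correlated at 0.960, and with the Matrigel plates at 0.929 to 0.941. Since no flow cell held both matrices, a property of the Matrigel flow cell and an effect of the matrix cannot be told apart.

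The rise of hypoxia and glycolysis genes was weighed against cell damage. In cells at or under their plate's median mitochondrial share the median log2 fold change of the hypoxia list was 0.59, against 0.76 over all kept cells. The median mitochondrial share was 13.3% in both matrices, and each plate was cut at its own median. The cut therefore removed no difference between the matrices, and cannot decide whether damaged cells played a part. In the cells of low mitochondrial share, 4 of 21 tested hypoxia genes passed the threshold. In the planned clustering, a cluster led by Bnip3 and Ndrg1 had the highest median mitochondrial share, 16.1%, against at most 14.7% in the others. It held 2.07%, 10.0% and 0% of cells on Matrigel plates 1 to 3. On collagen plates 1 to 3 it held 6.90%, 19.5% and 25.6%, so that a part played by damage stays open. With 25 cells drawn per plate the median of the hypoxia list was 0.46, a random draw that likewise cannot decide whether cell number played a part. An effect of the matrix on oxygen supply or metabolism was not tested and stays open, as does the flow cell.

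The fall of Cyr61, which went against Ctgf and the other YAP/TEAD targets that rose, was accompanied by falls of Fos, Fosb and Jun. Within the heat shock and dissociation stress list 5 genes rose and 5 fell, which decides nothing about a difference in dissociation stress. Immediate-early genes went both ways, with all 5 of the falls and 3 of the rises, among them Ier3. From cell to cell, the rank correlation of Cyr61 with 9 immediate-early genes exceeded that with the other 28 YAP/TEAD genes in 6 of 6 plates, by 0.3 ± 0.0868 on average (SD, exact sign-flip p = 0.0312). With all 15 members of the stress list that are not heat shock genes it did so in 6 of 6 plates, by 0.288 ± 0.133 (SD, exact sign-flip p = 0.0312, the smallest that 6 plates allow). Against 13 heat shock genes the correlation was higher in 6 of 6 plates for the 9 genes, by 0.375 ± 0.233 (SD, exact sign-flip p = 0.0312), but in 5 of 6 for the 15 genes, by 0.364 ± 0.297 (SD, exact sign-flip p = 0.0625). The 9 genes left out 3 that rose, so that noise shared by all stress genes of a cell stays open. Cyr61 may have followed the immediate-early response more than the other YAP/TEAD genes in these cells, which is a hypothesis found and tested on the same data. Whether that response differed in the organoids or arose in the minutes of dissociation cannot be read from these plates.

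For the number of changed genes, the real split of the 6 plates gave 1163, and the highest of the other splits gave 0, so that 1 of 10 splits gave a count as large. For gene lists by camera, the real split gave 17 and the highest other split 11, again 1 of 10. The other splits called 4 to 11 lists although 0 genes changed in them. Each of them put plates of both matrices in both groups. The difference between the matrices thus widened the spread within groups and also stayed in part between them. These splits therefore cannot show how many genes or lists would be called with no difference between the matrices. With 10 splits no share under 0.05 can be reached.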

How the results depend on the processing

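Leaving out both small plates, drawing 25 cells per plate, keeping cells of low mitochondrial share and clustering without the changed genes were chosen after the data were seen, and all other settings before. Against 1163 changed genes, the count lay between 1057 and 1711 with other normalizations, filters, inputs and cell limits and with DESeq2. It was 753 with plate sums thinned to the smallest, 187 with every cell thinned to 2000 UMIs (4725 genes tested), 199 with 25 cells per plate and 349 in cells of low mitochondrial share, settings that use fewer UMIs by construction. It was 2268 without both small plates, and ranged from 482 without Matrigel plate 3 to 1929 without collagen plate 1, with 643 without Matrigel plate 1, 500 without collagen plate 2 and 623 without collagen plate 3. With the plate number as a replicate block 609 genes changed, 600 of them shared, and 17 lists as before. Plates of the same number had correlations of deviations of -0.305, -0.153 and -0.0486, so that the numbers did not pair the plates. Of the 1163 genes, 1163 kept their sign without normalization factors and under the block, and 1156 of 1162 with read counts. With every cell thinned to 2000 UMIs 651 of 667 kept it, the weakest agreement. The calls shared were only 951 of 1163 without normalization factors, 626 of 1162 with read counts and 156 of 667 with every cell thinned.

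Lists called numbered 16 to 18 without 1 plate, 15 with 25 cells per plate, 9 with every cell thinned to 2000 UMIs and 0 with an estimated correlation, against 17. With 25 cells per plate the YAP/TEAD, calcium signalling and G2/M lists lost their call (limma camera adjusted p = 0.0922 each). With every cell thinned, the YAP/TEAD, Wnt, integrin, calcium signalling and EGFR/MAPK lists were tested and lost their call. Their limma camera adjusted p was 0.92, 0.221, 0.954, 0.295 and 0.49 in that order, with 8 tested YAP/TEAD and 5 tested integrin genes. Some other lists had too few tested members. Some lists gained a call, namely cytosolic ribosomal proteins without Matrigel plate 1, without collagen plate 1 and without both small plates, epithelial junctions without collagen plate 1, laminins with 25 cells per plate, Paneth genes with every cell thinned, and proteases in cells of low mitochondrial share. The per-cell G1/S difference ranged from -0.0427 to 0.0088 percentage points without 1 plate, where it turned without Matrigel plate 1 (0.0006) and collagen plate 1 (0.0088). The share of cells with at least 3 G2/M genes differed by 2.38 percentage points, by -3.16 at 1000 UMIs, by -0.256 at 4000 UMIs and by -0.266 with at least 2 genes. Non-overlapping anchor genes numbered 7 to 8 at other thinning depths and with the stricter mitochondrial limit, against 9. They numbered 10 to 12 without 1 plate, where fewer plates make non-overlap by chance more likely, so that these counts cannot be set against 9. With the plate number as a block, 10 genes had differences of the same sign in all plate pairs, which is a different measure. Clustering without cell cycle genes gave a cluster of 176 cells with 5 goblet markers, but with 4 Paneth against 3 goblet markers among its 10 leading genes. Its cells were not compared between matrices.

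Over 118 named genes, 2453 of 2677 combinations of a called gene and a setting kept the call and 224 lost it. The sign turned only for genes that were not called, with log2 fold changes of 0.021 with read counts, 0.10 without cells of many UMIs and 0.20 without both small plates for Krt20, of 0.13 with read counts and 0.18 with 25 cells per plate for Mki67, and of -0.40 with read counts for Cdh1. The cause was not tested. Depth limits genes under about 1 CPM, such as the channels Piezo2 and Trpv4.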

Other observations

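The retinoid, Notch, FGF, Ifitm, S100 and other genes given here were chosen after their values were seen, and the relations of hypoxia shares were computed only then.

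The retinol dehydrogenase gene Rdh10, which makes retinaldehyde, rose from 54.3 ± 4.39 to 197 ± 3.59 CPM (n = 3 plates, log2 fold change 1.87, SE 0.11, edgeR adjusted p = 5.64e-06), and Dhrs3, a retinaldehyde reductase gene, rose by 1.04 on the log2 scale (edgeR adjusted p = 0.0137), a call lost without collagen plate 2 (0.0752). Rdh9 fell by 0.72 and Aldh1b1 by 2.53 on the log2 scale. The receptor gene Notch1 fell from 36.8 ± 3.20 to 17.9 ± 2.60 CPM (n = 3, log2 fold change -0.97) and Hes6 from 202 ± 43.5 to 83.3 ± 13.6 CPM (n = 3, log2 fold change -1.30). The FGF receptor gene Fgfr4 fell by 1.03, while the ligand gene Fgf15 rose by 1.01 on the log2 scale. The neighbouring Ifitm1, Ifitm2 and Ifitm3 genes on chromosome 7 all fell, by 1.84, 0.96 and 1.35 on the log2 scale, and the neighbouring S100a14 and S100a16 genes on chromosome 3 rose by 1.39 and 1.51.

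Plk1 fell from 130 ± 8.46 to 77.2 ± 9.39 CPM (n = 3, log2 fold change -0.75) and Kif18b from 28.8 ± 2.74 to 12.4 ± 4.47 CPM (n = 3, log2 fold change -1.33). The oncofetal chromatin gene Hmga2 rose from 63.0 ± 8.14 to 124 ± 10.2 CPM (n = 3, log2 fold change 0.99).

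Within plates, hypoxia and fetal-like shares of single cells had negative rank correlations on 6 of 6 plates, between -0.258 and -0.0326. Whether they differed from no relation was not tested. Hypoxia and glycolysis shares were related on collagen plates 2 and 3, at rank correlations of 0.458 and 0.44, and lay between -0.222 and 0.0618 on the other plates (exact permutation p = 0.2 for the difference between matrices, n = 3). Collagen plate 1, with 29 cells, was at 0.0169.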
